A study of Homo sapiens with 4 samples.

How the data were processed

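RNA of MRC5 cells, an established line of human fetal lung fibroblasts, was measured in 4 libraries, 2 labelled as untreated (control) and 2 labelled as treated with miRs, all with 48 h in their titles. Groups were taken from the treatment label and replicate numbers from the titles. Per the labels' protocols, total RNA was purified on RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA and keeps the strand. The submitters' processing notes name TopHat2 2.1.1, Bowtie2 2.2.8, SAMtools 0.1.18, Cuffdiff 2.2.1 and the genome build hg19, without saying which step each served. The gene annotation, the strand setting and the way Cuffdiff scaled the libraries are not given in the sources used here. The deposited files hold 1 FPKM value per gene symbol and library, per the file headers, for 26255 genes. FPKM divides by transcript length and library size, so it is not a count, and estimates for genes with shared or overlapping transcripts depend on how fragments were assigned. Genes of small RNAs are shorter than the fragments of such a library, which makes their FPKM steep in few fragments.

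The number of reads per library is unknown. Ratios between libraries of genes under 0.3 FPKM in both were concentrated at simple ratios (51.7% to 55.9% of low genes within 1%), which gave the relative worth of 1 fragment per library. Whole reads were not recovered, because FPKM steps depend on the length of each gene's transcripts, so the planned count test was not run. Precision is therefore read from the 2 libraries per group, with 2 residual degrees of freedom.

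Genes with a mean of at least 1 FPKM over the 4 libraries (11860) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a moderated variance that follows mean expression, 2-sided, and Benjamini-Hochberg adjustment at a threshold of 0.05. Differences are miRs minus control on that scale. No scaling was added to that of the deposited values. Before the data were examined, 31 gene lists were fixed for a lung fibroblast line given microRNAs: interferon response, epithelial, endothelial, blood, smooth muscle and pericyte, neuronal and adipocyte markers, mesenchymal transcription factors, TGF-beta and myofibroblast genes, collagens, other extracellular matrix, YAP, p53 and NRF2 targets, cytokines, cell cycle (3 lists), histones, DNA methylation and chromatin, pluripotency, cholesterol synthesis, protein stress, heat shock, glycolysis, oxidative phosphorylation, ribosomal proteins, lysosome, apoptosis, microRNA machinery and growth factor signalling. The tests, the alternatives planned, the naming rule and 78 microRNA seed families were fixed at the same point.

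The 28 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. The other 3 (pluripotency, endothelial and blood) had too few. Camera with an estimated correlation and fry were alternatives. The former tests on at most the 2 residual degrees of freedom, so few lists could pass it. The text names the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, and, in each list described, up to 4 members with the smallest p plus members at a mean of at least 50 FPKM that go against the list's majority. ACTB, GAPDH, VIM and COL1A1 were fixed as checks. Other names are said to be chosen after their values were seen. Groups that do not overlap have both libraries of 1 group above both of the other.

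Alternatives were a pseudocount of 0.1, no minimum or a minimum of 5 FPKM, median-of-ratios rescaling, quantile normalization, no variance trend, the replicate number as a block, a log2 fold change of at least 1, and each library left out in turn. Chosen after the data were examined were fits without genes of short RNAs, a threshold of 0.1, 3 further lists and, for the 3′ UTR analysis, dinucleotide covariates and left-out libraries. The test was tested on simulated data for miRs against control. Each gene had the same spread in every library, drawn from the distribution of variances fitted to the real libraries, and genes varied independently. Over 11709 genes the test called 3 of 100 genes changed by 1 on the log2 scale, 70 of 100 changed by 2 and 3 of 11509 unchanged genes, and 0 in the wrong direction. The real miRs pair differed more than the control pair, which the simulation did not copy.

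For the 3′ UTR analysis, each gene's longest annotated 3′ UTR was taken by symbol from GENCODE 29, whose build differs from hg19, so no coordinates are given. Of the tested genes 91.1% (10805) had one of at least 20 bases. For each of the 16384 7-mers, the log2 difference was regressed across genes on presence of the 7-mer, with the log of UTR length, UTR GC share and mean expression as covariates, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and 7-mers were ranked by t, most negative first. Genes are not replicates, so t serves as a description. On simulated data over 10805 genes for miRs against control, with the differences shuffled between genes, a 7-mer given a log2 fall of 0.3 came out at rank 1. The coefficient of AGCACTT in the real data was smaller, at −0.106, and falls of that size were not simulated.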

Results

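Messenger RNA was measured by RNA sequencing in MRC5 cells, a line of human fetal lung fibroblasts, in 4 libraries: 2 labelled as receiving no treatment (control) and 2 labelled as treated with miRs, meaning microRNAs, which are short RNAs that pair with matching stretches of messenger RNAs, mostly in 3′ untranslated regions, and lower their level. The sample titles place all 4 at 48 h. The labels do not name the microRNAs. The series title sets a negative-control microRNA against the miRs while the treatment label of the control samples says that they had none, so it stays open whether the control cells received a control microRNA. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

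The values were FPKM (fragments per kilobase of transcript, scaled to the size of the library) for 26255 genes per library. The absolute number of reads is unknown, but steps between low values gave the relative worth of a fragment: 1 fragment was worth 1.05 times as much FPKM in control replicate 2 as in control replicate 1, 0.899 times in miRs replicate 1 and 1.03 times in miRs replicate 2. Relative to control replicate 1 the inverse, by which each library was scaled, was 0.952, 1.11 and 0.974, a narrow range. It equals relative depth only if the libraries were scaled by their fragment totals, which is not known. Between 11622 and 11781 genes per library reached 1 FPKM. Across genes, which are not independent replicates, Pearson's r of log2(FPKM + 1) was 0.985 between the control libraries and 0.949 between the miRs libraries. Among the tested genes, 71 lay over 2-fold apart between the 2 controls and 725 between the 2 miRs libraries.

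The comparison of miRs with control asks which transcripts respond when microRNAs are put into these fibroblasts. KRT18 and KRT19, keratins of simple epithelia, rose together with the tight-junction adhesion protein F11R, the annexin ANXA3 and the vesicle-fusion protein VAMP8. PLSCR3, a mitochondrial phospholipid scramblase, SYT11, a synaptotagmin of membrane traffic, CYBRD1, a ferric reductase, and the small GTPase RAB32 fell. The changes in these protein-coding genes were large, from 5.35-fold to 33.9-fold in mean FPKM for the 5 named rises and from 6.67-fold to 8.88-fold for the 4 named falls. The 33.9-fold of F11R rests on control values of 0.195 and 0.0559 FPKM and is imprecise. Of 11860 genes tested with limma, 29 passed an adjusted p of 0.05, 12 higher and 17 lower in miRs. The smallest adjusted p was 0.0204, for 3 genes of small nucleolar RNAs. Among the other called genes it was 0.0310, for SYT11, SYDE1 and AGPAT9. At an unadjusted p under 0.05 there were 2872 genes. In 7052 genes (59.5%, where chance gives 33.3%) both miRs libraries lay on the same side of both controls, 3499 above and 3553 below. The count of calls changed widely when 1 library was left out, the lone library being assumed to vary like the other group. With all libraries the count was 6 with quantile normalization and 0 in limma with no minimum FPKM, where 3338 genes had an unadjusted p under 0.05.

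KRT18 averaged 18.6 ± 1.24 FPKM in control and 166 ± 40.7 FPKM in miRs (SD, n = 2 each), a log2 fold change of 3.07 ± 0.21 (SE) with an adjusted p of 0.0354 in limma. KRT18 has many processed pseudogenes, so its level is uncertain. KRT19 went from 6.10 ± 0.0696 to 32.6 ± 4.10 FPKM (log2 fold change 2.24, adjusted p = 0.0354). ANXA3 went from 4.21 ± 1.20 to 40.6 ± 2.69 FPKM (log2 fold change 3.01, adjusted p = 0.0354) and VAMP8 from 1.11 ± 0.349 to 9.81 ± 0.239 FPKM (log2 fold change 2.37, adjusted p = 0.0430). F11R, barely detected in control at 0.126 ± 0.0985 FPKM, reached 4.26 ± 0.338 FPKM (log2 fold change 2.23, adjusted p = 0.0486). AGPAT9, an acyltransferase of triglyceride synthesis, rose 11.8-fold, F2RL1, a protease-activated receptor, 4.68-fold, and TPBG, a membrane glycoprotein of trophoblast, 4.20-fold. SMOX, the spermine oxidase, rose 3.90-fold, the protease inhibitor SERPINB7 3.59-fold, and TRIM25, a ubiquitin ligase of the RIG-I pathway of RNA sensing, 3.33-fold to 57.8 ± 3.45 FPKM. Fold changes in log2 are on the log2(FPKM + 1) scale and understate the change of low genes.

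Among the falls, PLSCR3 went from 51.7 ± 4.63 FPKM in control to 6.95 ± 1.22 FPKM in miRs (SD, n = 2 each; log2 fold change −2.73 ± 0.17, adjusted p = 0.0354 in limma). SYT11 went from 18.4 ± 1.66 to 2.07 ± 0.0913 FPKM (log2 fold change −2.66, adjusted p = 0.0310), CYBRD1 from 32.9 ± 2.63 to 4.48 ± 0.760 FPKM (−2.63, adjusted p = 0.0354) and RAB32 from 55.7 ± 4.43 to 8.35 ± 2.17 FPKM (−2.62, adjusted p = 0.0433). SYDE1 went from 43.1 ± 1.01 to 8.05 ± 0.235 FPKM (−2.29, adjusted p = 0.0310). RNASE4, a secreted ribonuclease, fell 8.16-fold, the delta-globin gene HBD 5.36-fold, the glutathione transferase GSTM3 4.99-fold, the bradykinin receptor BDKRB2 4.28-fold and ANO4, of the anoctamin family, 4.32-fold. CASS4, ATF6B, TMEM35, PRAF2 and TSEN34 fell as well, with log2 fold changes from −1.497 to −1.91. These 5 lie outside the naming rule and were named after their values were seen. Levels of RNASE4, which shares exons with ANG, of PLSCR3, which has a readthrough transcript with TMEM256, and of HBD and GSTM3, which have close paralogs, are uncertain.

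Of the 29 calls, 3 were genes of small nucleolar RNAs, which a library made from polyadenylated RNA captures poorly. SNORA27 was at 14.0 and 14.5 FPKM in control replicates 1 and 2 and listed at 0 in both miRs libraries. SNORA16A was at 11.2 and 11.6 FPKM in the controls and listed at 0 in both miRs libraries. SNORA67 was listed at 0 in both controls and at 37.0 and 53.2 FPKM in miRs replicates 1 and 2. The ratio of control replicate 2 to control replicate 1 was 1.03 for SNORA27 and 1.04 for SNORA16A, close to the 1.05 that equal numbers of fragments would give. For SNORA67 the ratio of miRs replicate 2 to miRs replicate 1 was 1.44, where equal numbers would give 1.14.

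**Figure D1:**
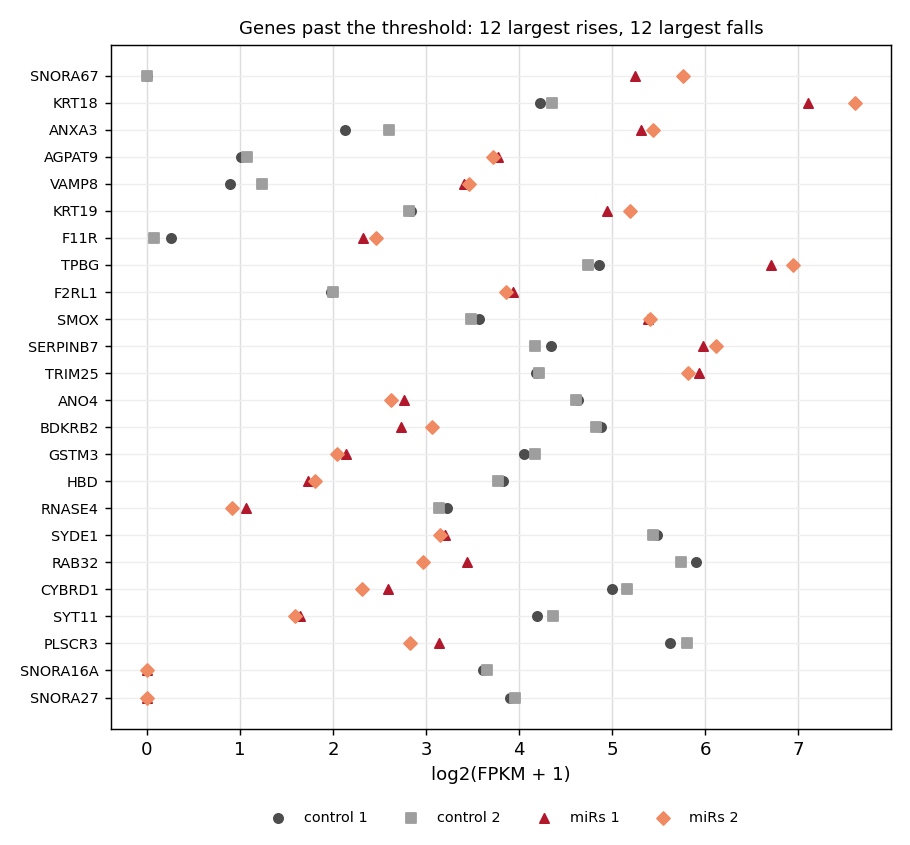
Expression of the 24 named genes past the threshold, with log2(FPKM + 1) on the x axis, genes on the y axis ordered by log2 fold change and 1 symbol per library. For KRT18 the control libraries sit at 17.7 and 19.4 FPKM and the miRs libraries at 137 and 194 FPKM, and for every gene drawn the 2 groups do not overlap.

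Genes of the interferon response made up most of the largest rises. MX1, a GTPase that blocks viruses, was at 0.920 and 1.35 FPKM in control replicates 1 and 2 and at 795 and 190 FPKM in miRs replicates 1 and 2. IFI6 was at 11.5 and 16.9 FPKM in control and 2750 and 580 FPKM in miRs, IFIT2, which binds foreign RNA, at 1.20 and 1.47 against 502 and 95.2 FPKM, and IRF7, the transcription factor that drives type I interferon genes, at 1.25 and 2.75 against 59.4 and 31.9 FPKM. The list's 36 members, all tested, had a median log2 difference of 4.80. Of the 50 genes with the largest positive log2 difference, 29 were on this list, and 9 of the top 10.

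In limma none of the 36 interferon genes passed over all genes, while 35 had an unadjusted p under 0.05 and 35 passed when adjusted over the list alone. The adjusted p over all genes was 0.0602 for MX1 and 0.0632 for IRF7, IFI6 and IFIT2. The 2 miRs libraries differed in the size of the response: the list's median difference from the mean of the controls was 6.0 in miRs replicate 1 and 3.39 in miRs replicate 2, and the median gap between these libraries was 2.31 (log2), against −0.13 between the controls. ISG15, a ubiquitin-like modifier, was at 3648 and 726 FPKM in the miRs libraries and 33.8 and 37.5 FPKM in the controls, and OAS1, a sensor of double-stranded RNA, was listed at 0 in both controls and at 227 and 19.96 FPKM in miRs. TRIM22 was the exception, at 34.5 and 36.0 FPKM in control and 91.9 and 25.3 FPKM in miRs (log2 difference 0.45, adjusted p = 0.681). ISG15, OAS1 and TRIM22 were named after their values were seen. The list was called higher by camera (adjusted p = 1.03e-20), and the call was lost when the correlation between its genes was estimated (adjusted p = 0.676 with an estimated correlation) and with fry (adjusted p = 0.176).

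**Figure D2:**
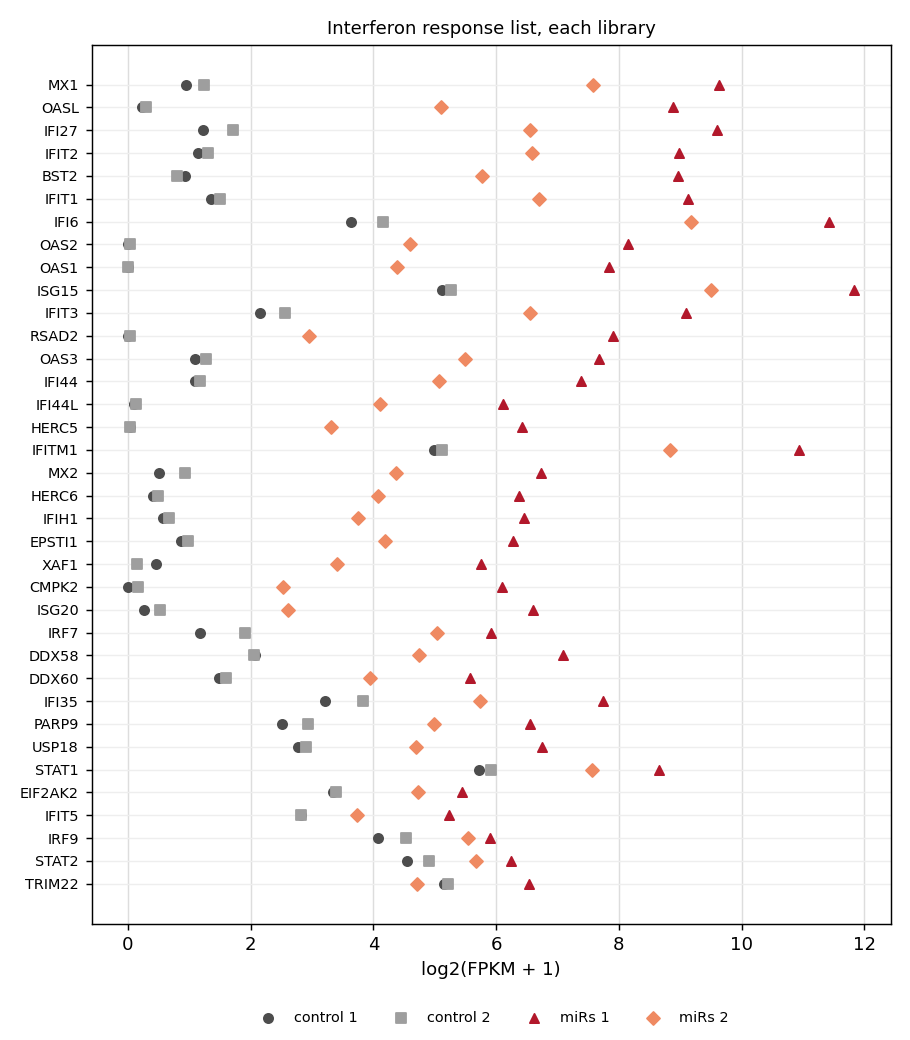
The 36 genes of the interferon response list, with log2(FPKM + 1) on the x axis, genes on the y axis ordered by log2 difference and 1 symbol per library. The miRs replicate 1 library lies above miRs replicate 2 for every gene, with MX1 at 795 and 190 FPKM, and TRIM22 is the gene whose miRs replicate 2 value falls below both controls.

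Of 23 epithelial cell markers, 6 reached the expression minimum, and all 6 were higher in both miRs libraries than in both controls, with a median log2 difference of 2.06 (1.80 in miRs replicate 1 and 1.90 in miRs replicate 2). The minimum is a mean over all 4 libraries, so a rise helps a low gene to reach it. With no minimum FPKM the median was 0.46 over 15 members, of which 0 passed over all genes in limma and 7 when adjusted over the list alone. KRT18 and KRT19 passed over all genes and 5 passed when adjusted over the list alone. KRT8, the partner keratin of KRT18, was at 4.47 and 5.07 FPKM in control and at 14.6 and 29.3 FPKM in miRs (adjusted p = 0.0863 in limma), and CLDN7, a claudin of tight junctions, at 0.596 and 0.974 against 3.99 and 3.19 FPKM (adjusted p = 0.0754). KRT8, like KRT18, has many pseudogenes and is uncertain. The list was called higher by camera (adjusted p = 2.89e-05; adjusted p = 0.676 with an estimated correlation). It was also called by fry, with an adjusted p of 0.0362. The epithelial cadherin CDH1, named after its values were seen, was at 0.0356 FPKM in control replicate 1 and listed at 0 in the other 3 libraries.

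The list of mesenchymal transcription factors, which also holds surface markers of fibroblasts, had 20 tested members with a median log2 difference of −0.42. FAP, a protease of activated fibroblasts, was at 32.2 ± 2.34 FPKM in control and 9.83 ± 2.71 FPKM in miRs (SD, n = 2 each; log2 difference −1.64, adjusted p = 0.0667 in limma). The cadherin CDH11 was at 41.6 ± 0.787 against 19.4 ± 2.82 FPKM (adjusted p = 0.0694), THY1, a fibroblast surface protein, at 370 ± 50.2 against 181 ± 9.07 FPKM (adjusted p = 0.0731), and ZEB2, a repressor of epithelial genes, at 10.99 ± 0.737 against 4.09 ± 1.25 FPKM (adjusted p = 0.0846). ENG, at 90.7 ± 6.83 against 151 ± 16.5 FPKM, and NT5E, at 190 against 398 FPKM on average, went the other way. No member passed over all genes, with 11 at an unadjusted p under 0.05, while 6 lower and 1 higher passed when adjusted over the list alone. The list was called lower by camera (adjusted p = 0.0422; adjusted p = 0.676 with an estimated correlation) and by fry (adjusted p = 0.0362), but not by camera with a minimum mean of 5 FPKM (adjusted p = 0.0589) or with quantile normalization (adjusted p = 0.0593).

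In the TGF-beta and myofibroblast list, 24 of 30 tested members had a lower mean in miRs, 19 of them with no overlap between the groups (3553 of all 11860 tested genes). The median log2 difference was −0.53 (−0.40 without miRs replicate 1 and −0.81 without miRs replicate 2). TGFBR2, the type II receptor of TGF-beta, was at 54.8 ± 0.346 FPKM in control and 22.8 ± 3.34 FPKM in miRs (SD, n = 2 each; log2 difference −1.24, adjusted p = 0.0632 in limma). Calponin CNN1 was at 85.7 ± 26.003 against 14.4 ± 4.42 FPKM (adjusted p = 0.0635), the smooth muscle actin ACTA2, whose close paralogs make it uncertain, at 475 ± 151.6 against 121 ± 8.19 FPKM (adjusted p = 0.0667), and the myosin light chain MYL9 at 949 ± 156 against 403 ± 5.99 FPKM (adjusted p = 0.0667). ID1, at 42.8 against 79.3 FPKM, and ID3, at 62.1 against 64.9 FPKM, both targets of BMP signalling, went against the majority. No member passed over all genes, with 17 at an unadjusted p under 0.05, while 13 lower and 3 higher passed when adjusted over the list alone. Camera called the list lower (adjusted p = 0.000330; adjusted p = 0.676 with an estimated correlation), and fry did not (adjusted p = 0.109).

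Smooth muscle and pericyte markers had a median log2 difference of −0.79 over 12 tested members and were not called (camera adjusted p = 0.0899). NOTCH3, a pericyte receptor, was at 31.5 ± 0.319 FPKM in control and 7.70 ± 2.05 FPKM in miRs (SD, n = 2 each), SYNPO2 at 10.9 ± 4.64 against 0.648 ± 0.353 FPKM, and LMOD1, an actin nucleator of smooth muscle, at 32.9 ± 1.91 against 5.18 ± 3.88 FPKM. CNN1 is on this list as well. CSPG4, at 49.2 against 65.5 FPKM, and MCAM, at 79.7 against 97.8 FPKM, were higher in miRs. In limma 0 members passed over all genes, 7 had an unadjusted p under 0.05, and 5 lower and 2 higher passed when adjusted over the list alone. The call was made without control replicate 1 (adjusted p = 0.0247), without control replicate 2 (adjusted p = 0.00521), without miRs replicate 1 (adjusted p = 0.0193) and with no minimum FPKM (adjusted p = 0.0446).

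Most genes on the mitotic list had a slightly higher mean log2 level in miRs, though the list's call depended on the test. In the list for G2/M and mitosis, 31 of 40 tested members were higher in both miRs libraries than in both controls, with a median log2 difference of 0.35. Of all 11860 tested genes, 3499 were higher in this way. Cyclin A2 (CCNA2) was at 24.8 ± 1.54 FPKM in control and 43.1 ± 1.89 FPKM in miRs, the kinetochore gene NDC80 at 11.1 ± 0.218 against 20.4 ± 2.59 FPKM, the phosphatase CDC25C at 3.96 ± 0.0753 against 7.56 ± 0.933 FPKM, and the mitotic kinase PLK1 at 34.6 ± 2.85 against 53.9 ± 1.41 FPKM (SD, n = 2 each). ANLN, at 64.0 against 57.4 FPKM, and BUB3, at 76.0 against 73.2 FPKM, went against the majority. In limma 0 of the 40 passed over all genes, 19 had an unadjusted p under 0.05, and 5 passed when adjusted over the list alone. Camera called the list higher (adjusted p = 6.59e-07; adjusted p = 0.676 with an estimated correlation), and fry did not (adjusted p = 0.159).

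In the list for G1/S and DNA replication, 18 of 40 tested members were higher in both miRs libraries than in both controls (3499 of all 11860 tested genes). The median log2 difference was 0.26 (0.12 without miRs replicate 1). CDC25A, a phosphatase that activates cyclin-dependent kinases, was at 3.02 ± 0.176 FPKM in control and 8.93 ± 2.67 FPKM in miRs, RFC4 at 13.3 ± 0.495 against 21.8 ± 3.07 FPKM and the licensing factor CDT1 at 7.68 ± 0.503 against 13.6 ± 2.48 FPKM (SD, n = 2 each). The transcription factor E2F1, at 9.08 ± 0.780 against 5.44 ± 1.01 FPKM, was lower in miRs, as were RRM2, at 52.0 against 49.0 FPKM, and MCM7, at 57.9 against 56.2 FPKM. In limma 0 members passed over all genes or adjusted over the list alone, and 9 had an unadjusted p under 0.05. Camera called the list higher (adjusted p = 0.00433; adjusted p = 0.760 with an estimated correlation). Without miRs replicate 1 the call was lost (adjusted p = 0.198), and fry did not make it (adjusted p = 0.374).

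The list for DNA methylation and chromatin (38 tested, median log2 difference 0.18) was called higher by camera (adjusted p = 0.0289; adjusted p = 0.676 with an estimated correlation). The call was not made by fry (adjusted p = 0.147), without miRs replicate 2 (0.177) or with a minimum mean of 5 FPKM (0.0589). The DNA methyltransferases DNMT3A and DNMT3B were at 4.41 ± 0.0204 and 1.21 ± 0.126 FPKM in control and at 8.31 ± 1.34 and 3.47 ± 0.914 FPKM in miRs (SD, n = 2 each). The histone demethylase KDM6A was at 3.26 ± 0.0745 against 6.10 ± 0.959 FPKM and the DNA glycosylase TDG at 8.41 ± 1.51 against 14.3 ± 0.713 FPKM. In limma 0 members passed over all genes or adjusted over the list alone, and 10 had an unadjusted p under 0.05.

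Matrix genes moved in both directions and their lists were not called. In the list of other extracellular matrix and its enzymes (43 tested, median log2 difference −0.24, camera adjusted p = 0.125), the protease ADAMTS1 was at 169 ± 29.2 FPKM in control and 47.1 ± 0.768 FPKM in miRs, the metalloproteinase inhibitor TIMP2 at 318 ± 4.73 against 77.8 ± 24.3 FPKM, thrombospondin THBS1 at 397 ± 17.8 against 119 ± 30.2 FPKM and decorin (DCN) at 1093 ± 184 against 385 ± 47.4 FPKM (SD, n = 2 each). SPARC, MMP1, NID1, SERPINH1, LAMA4, TIMP3, LAMC1, LAMB1, MMP14, FBN1 and NID2 went against the list's majority, with log2 differences from 0.02 for NID2 to 1.02 for MMP1. In limma 0 members passed over all genes, 14 had an unadjusted p under 0.05, and 4 lower and 2 higher passed when adjusted over the list alone. Without control replicate 2 the list was called lower (adjusted p = 0.0170).

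Among 19 tested fibrillar and network collagens (median log2 difference −0.07, or 0.06 under quantile normalization; camera adjusted p = 0.995), COL4A2 of basement membranes was at 344 FPKM in control and 207 FPKM in miRs and COL12A1 at 226 against 136 FPKM, while COL11A1 was at 10.6 against 23.9 FPKM and COL5A3 at 5.37 against 8.96 FPKM. COL1A1, COL3A1, COL5A1 and COL8A1 also had a higher mean in miRs, by 0.08 to 0.34 (log2), with overlapping groups. In limma 0 collagens passed over all genes, 4 had an unadjusted p under 0.05, and COL4A2 and COL11A1 passed when adjusted over the list alone. The 2 miRs libraries differed here: the list was called higher without miRs replicate 1 (adjusted p = 0.0410) and lower without miRs replicate 2 (adjusted p = 0.0347).

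YAP targets (18 tested, median log2 difference −0.29) were not called (camera adjusted p = 0.128), except without miRs replicate 2 (adjusted p = 0.0120, median −0.67); without miRs replicate 1 the median was −0.04. LATS2, a kinase of the Hippo pathway, was at 14.6 ± 0.293 FPKM in control and 4.51 ± 1.12 FPKM in miRs, CRIM1 at 171 ± 8.12 against 66.9 ± 24.7 FPKM and AMOTL2 at 68.3 ± 1.35 against 37.9 ± 4.49 FPKM (SD, n = 2 each). ANKRD1, at 0.612 ± 0.314 against 5.05 ± 0.816 FPKM, NT5E and AXL, at 205 against 250 FPKM, were higher in miRs. In limma 0 members passed over all genes, 7 had an unadjusted p under 0.05, and 6 lower and 1 higher passed when adjusted over the list alone.

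Cytokines and NF-kB targets (18 tested, median log2 difference 0.21, camera adjusted p = 0.879) differed between the miRs libraries, with a median of 0.94 in miRs replicate 1 and −0.46 in miRs replicate 2. PTGS2, the inducible cyclooxygenase, was at 0.325 and 0.161 FPKM in control and 5.26 and 4.05 FPKM in miRs, while the cytokine LIF was at 20.6 and 19.4 against 5.76 and 7.23 FPKM, the chemokine CCL2 at 95.4 and 42.2 against 11.5 and 6.03 FPKM and the adhesion molecule VCAM1 at 7.74 and 4.94 against 1.77 and 2.38 FPKM. SOD2 was at 63.5 and 63.4 FPKM in control and 110 and 35.6 FPKM in miRs. In limma 0 members passed over all genes, 7 had an unadjusted p under 0.05, and 1 higher and 3 lower passed when adjusted over the list alone. The list was called higher without miRs replicate 2 (adjusted p = 0.00295).

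Among p53 targets (27 tested, median log2 difference 0.14, camera adjusted p = 0.274), MDM2, which degrades p53, was at 16.5 and 15.9 FPKM in control and 29.1 and 31.8 FPKM in miRs, the apoptosis gene BBC3 at 5.95 and 6.24 against 13.4 and 23.8 FPKM and TRIAP1 at 22.0 and 24.6 against 37.1 and 36.3 FPKM, and these 3 passed when adjusted over the list alone. The cell cycle inhibitor CDKN1A, also a p53 target, was at 527 and 529 FPKM in control and 197 and 310 FPKM in miRs (log2 difference −1.09, adjusted p = 0.102 in limma), and BAX was at 192 and 203 against 190 and 204 FPKM. In limma 0 p53 targets passed over all genes and 8 had an unadjusted p under 0.05. Without miRs replicate 1 the list was called higher (adjusted p = 0.00893, median 0.22), and without miRs replicate 2 its median was −0.09. In the list of G1 cyclins, CDKs and inhibitors (18 tested, median −0.10, camera adjusted p = 0.470), RBL2, which restrains E2F, was at 10.8 and 10.9 against 6.18 and 6.48 FPKM, CDKN2B at 2.31 and 2.45 against 0.878 and 1.47 FPKM and MYC at 19.4 and 19.7 against 42.3 and 27.2 FPKM, and 0 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05. Of 18 pluripotency genes only KLF4 and MYC reached the minimum, too few for a list test. KLF4, a reprogramming factor that also acts in epithelia, was at 1.59 and 1.61 FPKM in control and 25.4 and 12.7 FPKM in miRs (log2 difference 2.87, adjusted p = 0.0632), and both passed when adjusted over the list alone.

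The other lists were not called by camera. Median log2 differences were 0.29 for unfolded protein and amino acid stress (adjusted p = 0.232), 0.40 for replication-dependent histones (0.382), 0.17 for apoptosis regulators (0.186), 0.14 for heat shock (0.508), 0.13 for microRNA machinery (0.265), 0.12 for adipocyte and lipid droplet genes (0.400), 0.12 for cholesterol synthesis (0.709) and 0.04 for neuronal genes (0.995). They were −0.35 for NRF2 targets (adjusted p = 0.140), −0.09 for ribosomal proteins (0.309), −0.06 for growth factor receptors and PI3K/RAS signalling (0.995), −0.04 for nuclear-encoded oxidative phosphorylation (0.186), −0.04 for lysosome and autophagy (0.924) and −0.02 for glycolysis and hypoxia (0.995, with a median of 0.07 under quantile normalization). Adjusted over the list alone, 4 lower and 2 higher members of the growth factor list, 3 higher and 1 lower of the glycolysis list, 2 higher adipocyte genes, 1 higher apoptosis regulator, 1 higher cholesterol gene, 1 lower stress gene and 1 lower neuronal gene passed, and 0 in the other 7 lists. In limma none of these 14 lists had a member past the threshold over all genes. In 10 of the 14 the median changed sign when 1 library was left out, the exceptions being unfolded protein stress, microRNA machinery, neuronal genes and oxidative phosphorylation. For NRF2 targets it was 0.07 without miRs replicate 1 and −0.67 without miRs replicate 2. Without miRs replicate 2 the NRF2 list (adjusted p = 0.000566) and the ribosomal proteins (adjusted p = 6.49e-05) were called lower and the apoptosis regulators higher (adjusted p = 0.00719). Without miRs replicate 1 the ribosomal proteins (adjusted p = 0.0498), the cholesterol (0.0263), unfolded protein (0.0152) and adipocyte (0.0193) lists were called higher, and without control replicate 1 the NRF2 list lower (0.0377).

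Markers of other cells gave little. Of 14 endothelial markers 4 reached the minimum (median log2 difference 0.05), and ESAM, at 0.296 and 0.310 FPKM in control and 3.68 and 1.62 FPKM in miRs, was the member that passed when adjusted over the list alone. Of 15 blood cell markers only CD68, a lysosomal protein that fibroblasts also express, reached the minimum, at 53.8 and 57.6 FPKM in control and 130 and 41.9 FPKM in miRs. Camera called 7 of the 28 tested lists, and 0 of the 7 calls held with an estimated correlation, where 1 list had an unadjusted p under 0.05 and the adjusted p values of the called lists ran from 0.676 to 0.760. Fry, which asks whether a list's genes move on balance 1 way, called 2 lists.

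**Figure D3:**
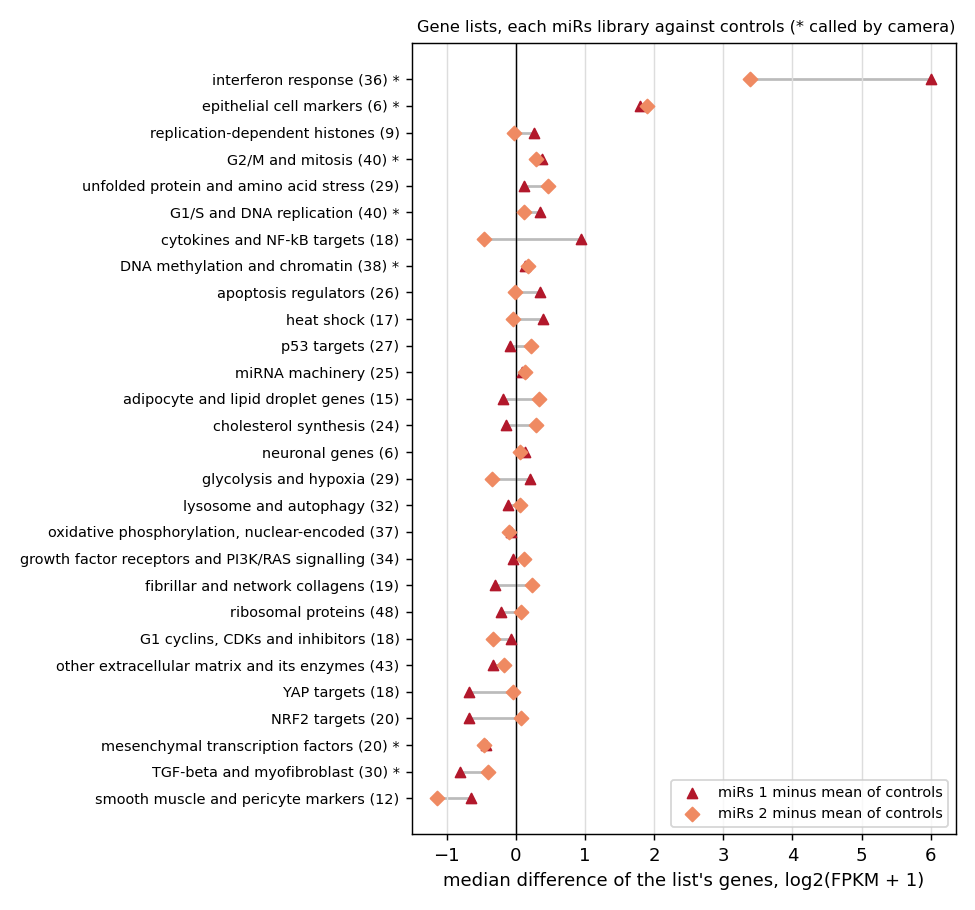
Median difference in log2(FPKM + 1) between each miRs library and the mean of the controls (x axis) for the 28 tested lists (y axis, genes tested in brackets), with 1 symbol per miRs library and a grey line joining the pair. The interferon list stands apart at 6.0 and 3.39, the epithelial list lies at 1.80 and 1.90, and an asterisk marks the 7 lists called by camera with a preset correlation.

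Among the genes fixed as housekeeping checks, ACTB was at 5648 and 5619 FPKM in control and 3022 and 3679 FPKM in miRs (log2 difference −0.76, adjusted p = 0.0937 in limma). VIM, the intermediate filament of mesenchymal cells, was at 3697 and 3170 FPKM in control and 2598 and 2249 FPKM in miRs (−0.50, adjusted p = 0.159), and GAPDH at 6135 and 5526 against 4736 and 4421 FPKM (−0.35, adjusted p = 0.213), a difference that vanished under quantile normalization. That normalization gives equal ranks equal values, so for GAPDH, among the highest genes of each library, it is a weak check. COL1A1 was at 2337 and 2521 FPKM in control and 1910 and 4742 FPKM in miRs (adjusted p = 0.700), below both controls in miRs replicate 1 and above both in miRs replicate 2. ACTB and GAPDH have many pseudogenes and are uncertain. The median log2 difference of all tested genes was −0.002 as deposited, 0.003 after median-of-ratios rescaling and −0.014 after quantile normalization. Neither rescaling turned a direction given for a called gene or list. Median-of-ratios factors of the deposited values lay between 0.999 and 1.005, so that rescaling could change almost nothing and is no check.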

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

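Fits without genes of short RNAs, the threshold of 0.1 and, for the 3′ UTR ranks, dinucleotide covariates and left-out libraries were chosen only after the data were examined. The count of 29 genes stayed between 20 and 35 with a pseudocount of 0.1, a minimum of 5 FPKM, median-of-ratios rescaling, no variance trend, a log2 fold change of at least 1 and without short RNA genes. It was 0 in limma with no minimum FPKM (3338 genes at an unadjusted p under 0.05), and the cause was not tested. It was 6 with quantile normalization, where the other 23 called genes had adjusted p values from 0.0502 to 0.0563; and 854 at a threshold of 0.1, which contains the smaller set by construction. Leaving out 1 library gave 0 to 3746 genes: 0 without control replicate 1 (886 at an unadjusted p under 0.05), 1 without control replicate 2, 1653 without miRs replicate 1 and 3746 without miRs replicate 2, and the last 2 each held the 29 genes of the full set. By construction, the spread then comes from the group that kept both libraries, and the miRs pair differed more than the control pair. With the replicate number as a block, 99 genes passed (41 higher, 58 lower), including all 29, and 10 lists, the 3 further ones being smooth muscle and pericyte markers (adjusted p = 0.0357), other extracellular matrix and NRF2 targets (0.0444 each), all lower. The same-numbered libraries share only a number in the labels. Across genes, the deviations of the replicate 1 libraries from their group means had a correlation of 0.20. With 2 libraries per group, replicate 2 mirrors this by construction. Camera called 6 to 8 lists in place of 7 with a pseudocount of 0.1, no minimum, either rescaling, no variance trend and without short RNA genes, and 4 with a minimum of 5 FPKM, where the epithelial list kept 3 members, too few to test. The chromatin and mesenchymal lists were at an adjusted p of 0.0589 there, and the cause was not tested. Leaving out 1 library gave 9 to 13 lists. With an estimated correlation 0 lists were called (1 at an unadjusted p under 0.05). That variant tests on at most the 2 residual degrees of freedom, so few lists could pass. The estimated correlation was −0.031 for the epithelial and −0.048 for the mesenchymal list, below the preset 0.01. A higher correlation therefore does not account for the loss of those calls. For the other called lists it was above the preset, up to 0.96 for interferon. Fry called 2 lists, and the cause was not tested. In 3 cases a direction turned, with an adjusted p under 0.05 in the refit, when 1 miRs library was left out. Over the 4 refits without 1 library, the collagen list had an unadjusted p from 0.0149 (lower, without miRs replicate 2) to 0.953 (without control replicate 2) and was higher without miRs replicate 1 (0.0161), the ribosomal proteins ran from 6.95e-06 (lower, without miRs replicate 2) to 0.382 (without control replicate 2) and were higher without miRs replicate 1 (0.0231), and SOD2 ran from −0.82 without miRs replicate 1 to 0.78 without miRs replicate 2 (log2), since its values in the 2 miRs libraries lie on opposite sides of the controls. Over the 208 named genes, 2078 of 2471 refits kept both direction and side of the threshold, 49 turned without a call before or after, 123 lost and 220 gained the call, and 1 turned with a call. Over the 28 lists it was 320, 31, 17, 19 and 2 of 389. The rank of AGCACTT stayed at 2 to 3 in every refit. The planned count test was not run, because whole reads were not recovered. With 2 libraries per group the simulated test, which gave both groups the same spread, found 3% of genes changed by 1 and 70% of those changed by 2 on the log2 scale. In that setting changes near 2-fold were mostly out of reach. The shares for the real libraries, with their wider miRs pair, are unknown, and depth cannot be stated as reads.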

Other observations

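The lists for antigen presentation, for interferons with their sensors and for actin, and the tests of the places among 7-mers of the same bases, dinucleotide covariates, site counts in called genes, scaling, CDH1, interferon and ZEB1 as explanations, were chosen only after the results were seen. The ranking of the 7-mers was planned. Genes of antigen presentation had a median log2 difference of 1.11 over 17 tested members, 13 of them higher in both miRs libraries than in both controls. Of all 11860 tested genes, 3499 were higher in this way. TAP1, the peptide transporter, was at 17.9 and 16.6 FPKM in control and 179 and 41.0 FPKM in miRs, the immunoproteasome gene PSMB9 at 5.14 and 9.18 against 113 and 14.9 FPKM, and beta-2-microglobulin (B2M) at 1007 and 972 against 3715 and 1227 FPKM. In limma 0 of the 17 passed over all genes or adjusted over the list alone, with 4 at an unadjusted p under 0.05; camera's adjusted p over the 3 lists was 4.62e-05, and adjusted p = 0.386 with an estimated correlation. The interferon gene IFNB1 was listed at 0 in both controls and at 9.95 and 0.660 FPKM in miRs replicates 1 and 2, and IFNL1 was listed at 0 in both controls and in miRs replicate 2 and stood at 9.48 FPKM in miRs replicate 1; IFNL1 has close paralogs and is uncertain. The 7 tested interferon and sensor genes had a median of 1.46 (camera adjusted p = 0.00458; adjusted p = 0.386 with an estimated correlation), with DHX58 at 1.05 and 1.64 FPKM in control and 20.7 and 5.09 FPKM in miRs.

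Genes of actin and its regulators had a median log2 difference of −0.47 over 22 tested members, 17 of them lower in both miRs libraries than in both controls. Of all 11860 tested genes, 3553 were lower in this way. CFL2, an actin-severing protein, was at 55.5 and 51.1 FPKM in control and 13.1 and 8.63 FPKM in miRs (log2 difference −2.22, adjusted p = 0.0632 in limma), and the cytoplasmic actin ACTG1, uncertain for its pseudogenes, at 3415 and 3408 against 1237 and 2001 FPKM (−1.12, adjusted p = 0.107). ACTN1, which crosslinks filaments, had a log2 difference of −0.93 (adjusted p = 0.0668). Profilin (PFN1) was at 1174 and 1022 against 1056 and 1134 FPKM, and the actin-binding TMSB4X, at 2850 and 2751 against 3191 and 2899 FPKM, and TPM3, with a log2 difference of 0.12, had a higher mean in miRs. No member passed over all genes in limma, 11 had an unadjusted p under 0.05 and 7 passed when adjusted over the list alone. Camera's adjusted p was 3.07e-06, and adjusted p = 0.177 with an estimated correlation. The list was chosen after the results were seen and holds ACTB, already seen lower, so its camera p is no independent support.

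Transcripts with certain 7-base sites in the 3′ UTR were lower in miRs than other transcripts. Across 10805 genes the lowest t of any 7-mer was that of GCACTTA (−9.94), and AGCACTT, the site of the miR-302-type seed, came next (−7.24). Both hold GCACTT, as does the miR-17 site GCACTTT, so the ranks of these sites are not independent. Among the 630 7-mers made of the same bases, AGCACTT was at rank 2 behind GCACTTA (0.317%, the site itself counted). Its t stayed at −7.66 with dinucleotide shares in the model, which argues against base composition of the 3′ UTR as the cause. The sites of miR-200b/200c (1 of 420, 0.238%, rank 23) and miR-369-3p (1 of 105, 0.952%, rank 13) also stood low among 7-mers of their own bases, the site itself counted. So did those of miR-17 (2 of 420, 0.476%, rank 9), miR-19 (3 of 420, 0.714%, rank 10) and miR-203 (2 of 210, 0.952%, rank 38). The percents depend on how many 7-mers the bases allow. Among the 7692 genes without AGCACTT and GCACTTA these 5 were at ranks 103, 56, 121, 71 and 213. In miRs replicates 1 and 2 taken singly they were at 18 and 38, 13 and 18, 124 and 5, 4 and 21, and 16 and 179. Of the 14 called lower genes with a 3′ UTR, which contribute to these ranks, 8 carried AGCACTT (57.1%, against 25.2% of all genes) and 8 GCACTTA (57.1% against 9.52%). The miR-200b/200c site was in 4 of the 14 (28.6% against 19.5%) and the miR-369-3p site in 1 (7.14% against 15.1%). A mixture holding miR-302-type microRNAs may lower these transcripts, as a hypothesis, and whether miR-200-type, miR-369-type, miR-17-type or miR-19-type microRNAs are in it stays open: the labels do not name them, AU-rich 7-mers such as ATTTATT (rank 3) fell too, and miR-200 and miR-369 were picked for their known use beside miR-302 in reprogramming, not by rank alone. At the other end of the ranking, the miR-29 site had a t of 4.36 (rank 16383), and the largest t of any 7-mer was 4.69. The miR-200b/200c site had −3.97 and the miR-369-3p site −4.46, so a t near that size arose in both directions.

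The interferon response list was higher in both miRs libraries and more so in replicate 1. Scaling by 1 factor per library, which moves every gene alike, is argued against by a list median 4.80 (log2) above the median of all tested genes, and blood cells in the miRs libraries by their markers, of which 1 of 15 reached 1 FPKM in both. What stays open is a response to the miRs themselves, to RNA or reagent entering the cells, which depends on whether the control cells were transfected, a stronger action of the miRs in replicate 1, although the fall with AGCACTT was −0.08 there and −0.13 in replicate 2, and a difference between the 2 cultures or libraries.

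The 6 tested epithelial genes, KRT18 and KRT19 among them, were higher in miRs, with a median of 1.80 in replicate 1 and 1.90 in replicate 2 (0.46 over 15 genes with no minimum FPKM). Epithelial cells in the miRs libraries are argued against by the epithelial cadherin CDH1, listed at 0 in both (highest value 0 FPKM). A response to interferon in proportion to the interferon list is argued against by the gap between miRs replicate 1 and miRs replicate 2, −0.12 for the epithelial list against 2.31 for the interferon list; a response already at its ceiling in replicate 2 was not tested. A candidate explanation is release from ZEB1 and ZEB2, repressors of epithelial genes and known targets of the miR-200 family: ZEB1 was at 44.3 and 36.7 FPKM in control and 15.6 and 6.90 FPKM in miRs (log2 difference −1.85, adjusted p = 0.0950 in limma). That did not pass the threshold and moved with the treatment like every other difference, so lower ZEB1 and ZEB2 cannot be told apart from other effects of the miRs. Not every epithelial gene rose: CDH1 was listed at 0 FPKM in both miRs libraries, so a release, if there was one, did not extend to it.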
